A study of Mus musculus and Homo sapiens with 16 samples.

How the data were processed

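The series held 16 ATAC-seq libraries, 1 peak list per library. Per the labels, neuronal nuclei were sorted with an antibody to NeuN from adult mouse cortex, astrocytes were purified from adult cortex with ACSA-2 beads, HEK293T cells were grown as wells of a control and a SETDB1 knockout line, and each reaction used 50000 nuclei. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.7, Bowtie2 2.4.1, SAMtools 1.6 and MACS2 2.2.7.1, with the builds mm10 and hg38. The settings of the peak caller, the filters on reads and whether reads were shifted for the transposase are not given in the sources used here. A change of these settings would move the number, width and edges of peaks in every list.

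Each deposited list is in the narrowPeak layout. The deposited values are a display score, a fold enrichment over local background (a ratio), the -log10 of the p-value and of the q-value, and the offset of the summit in bases (another unit, a position). The authors called peaks in each library by itself as far as the layout shows. The smallest -log10 q in the deposited lists lay between 1.30 and 1.44. Folds and p-values of separate lists depend on depth, so they were used only to describe, rank or select peaks within a list. Mean folds over lists are given to describe a peak and were not compared between groups.

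Groups were taken from the labels: wildtype and knockout neurons (3 animals each, replicates 1 and 2 in batch 1 and replicate 3 in batch 2), control and knockout HEK293T cells (3 wells each), and astrocytes labelled wildtype and knockout (2 samples of 2 animals each). In the 4 astrocyte lists the genotype in the peak names is the opposite of that in the labels, and the labels were kept. The HEK293T wells of a group come from 1 line, so permutation p-values of that comparison measure the spread between wells. Fisher's exact tests count regions and measure no spread between libraries.

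Peaks on the autosomes and X of all libraries of a comparison were merged where they shared 1 base or more. A region was gained when it had a peak in every knockout and no control library, and lost in the reverse case. The comparison regions of each test were those with a peak in exactly as many libraries as 1 group has, since only these could have been gained or lost. Gained and lost regions were counted against all other splits of the same libraries (10 splits of 6 libraries, 3 of 4). Values per library were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3, 0.333 with 2 against 2 and 0.0167 for the difference between neurons and astrocytes. A single region cannot pass a test at these numbers, so only sets of regions were tested, by Fisher's exact test (two-sided for lists, one-sided for windows of 1 Mb with 5 or more comparison regions) with Benjamini-Hochberg adjustment at 0.05.

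Gene positions came from a table of 21883 protein-coding genes of GRCm38.p6, the assembly behind mm10. It gives no strand, so the planned promoter shares and nearest start sites were replaced by the share of summits within 1 kb of either end of a gene and by the nearest gene end. No human annotation was used here, so HEK293T regions are given by position and by 4 loci written down in advance. The 22 gene lists, applied to gene bodies extended by 10 kb, were clustered protocadherins (58 genes), zinc finger genes (399), germline genes (29 matched), MAGE and other cancer-testis families (33), imprinted genes (30), interferon response (40), cytokines and inflammasome (34), complement and antigen presentation (23), reactive astrocyte genes (28), activity-induced genes (24), glutamate receptors and synapse (30), GABA receptors and interneurons (28), monoamine, stress axis and neuropeptide genes (31), markers of neurons (20), astrocytes (20), the oligodendrocyte lineage (18), microglia (23) and vessels (18), Hox genes (39), SETDB1 partners (22), olfactory receptors (1117) and housekeeping genes (17).

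The text names, per comparison and direction, from the 10 gained and 10 lost regions with the highest mean within-list rank by p (named by the gene with the nearest end within 100 kb), up to 10 list genes with an end within 1 kb of a gained or lost region, Setdb1, and the 3 windows with the smallest p. The groups, lists, loci, tests, naming rule and most alternatives were set before the data were examined. The positions of the 9 gained protocadherin regions and the shares of chromosomes were described after their values were seen.

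The lists hold no read counts. From the deposited fold and p of each peak, the pileup at its summit and the local background were recovered, taking a pileup as whole when it lay within 0.1 of a step of a whole number. All peaks (100%) passed in every library, and of 20000 simulated peaks with p moved at random 20.1% did. The most frequent background pileup then describes depth. The smallest pileup called as a peak was 5 to 6 reads in astrocyte libraries and 9 to 13 in the others, so an absent peak does not mean closed chromatin. These are the lowest values of whole lists. Where the local background is higher, a region can hold more reads than this and still have no peak.

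The alternatives were peaks with a -log10 q of 5 or more, equal list length (the strongest peaks by p, as many as in the shortest list), 50% of a region covered, windows of 250 bp around summits, a stricter threshold for presence than for absence, autosomes only, other gene extensions and window sizes, batch 1 only, blocks by batch or replicate number, and each library left out in turn. Gene-end shares, counts at named loci, tests within a chromosome and the recovered pileup were added after the files were seen. So was the expected overlap of neurons and astrocytes over regions that could have been gained or lost in both, used in place of the planned one over all regions with a peak in both.

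The procedure was tested on simulated presence tables in which 200 regions, 20 of them at 1 list, were made to be gained. Since the implanted regions meet the definition of gained, their recovery (200 of 200) checks only that the code counts them and says nothing of sensitivity. That list passed its test in the neuron, HEK293T and astrocyte simulations (101647, 135218 and 66174 regions). With nothing implanted, presence drawn at random gave 515 gained and 521 lost regions for neurons, 726 and 717 for HEK293T cells and 1367 and 1364 for astrocytes, and 0, 0 and 1 lists were called. Each region was drawn by itself in each library. The draws thus hold no neighbouring regions that change together, no unequal list lengths and no batches. They cannot show how often lists are called falsely where these are present. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.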

Results

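Open chromatin was profiled by ATAC-seq, which marks accessible DNA by the insertions of a transposase, in 16 libraries with and without SETDB1, a methyltransferase of histone H3 lysine 9. Neuronal nuclei sorted for NeuN from adult mouse cortex came from 3 wildtype animals and 3 animals of the Setdb1 knockout genotype. HEK293T cells, an established human embryonic kidney line, gave 3 replicate wells of a control line and 3 of a SETDB1 knockout line. Cortical astrocytes purified by the surface antigen ACSA-2 gave 2 samples per genotype, each of 2 animals combined. The 6 neuronal lists held 48122 to 86128 peaks on the autosomes and X, the 6 HEK293T lists 61357 to 85331, and the 4 astrocyte lists 45305 to 54602. Read totals were not used here, so depth was described by the most frequent local background pileup under the peaks. This pileup was 2.27 to 4.58 reads in the neuronal libraries, 2.34 to 3.38 in HEK293T cells and 0.9 to 1.05 in astrocytes.

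**Figure D1:**
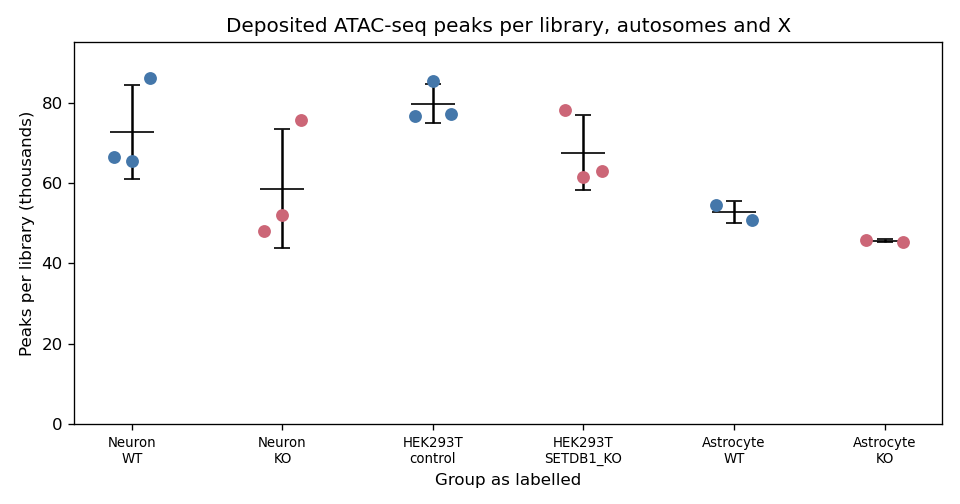
Number of peaks per library (vertical axis, divided by 1000) for the 6 groups as labelled. Points are libraries, horizontal bars group means and whiskers 1 SD. The neuronal groups overlap, with 48122 to 75574 peaks in the knockout and 65463 to 86128 in the wildtype libraries, whereas both astrocyte libraries labelled knockout lie below both labelled wildtype.

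The Setdb1 gene itself (chromosome 3, 95323525 to 95357202, mm10) had a peak at its upper end in all 10 mouse libraries. The fold enrichment of this peak over local background is a value from the authors that depends on depth, and it was not compared between groups. Its mean over lists was 8.16 ± 0.924 (SD, n = 3) in wildtype and 9.50 ± 0.353 (n = 3) in knockout neurons. It was 12.2 ± 0.487 (n = 2) in astrocyte libraries labelled wildtype and 12.4 ± 1.16 (n = 2) in those labelled knockout. A peak at a gene end does not show whether an exon was deleted, so the knockout could not be checked from these lists.

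Markers of the sorted cell types followed the cell type labels. Of 20 neuronal markers such as Slc17a7 and Neurod6, 18 ± 1 had a peak at a gene end in wildtype and 16.7 ± 0.577 in knockout neurons (n = 3 each), against 9.5 ± 0.707 and 9 ± 1.41 in astrocyte libraries labelled wildtype and knockout (n = 2 each). Of 20 astrocyte markers such as Aqp4 and Gja1, 10 ± 1 had such a peak in both neuronal groups and 17 ± 0 in both astrocyte groups. Of 18 oligodendrocyte lineage markers, 13.5 ± 2.12 had a peak in astrocyte libraries labelled wildtype and 11.5 ± 2.12 in those labelled knockout, against 5 ± 1 and 3.67 ± 2.08 in wildtype and knockout neurons. Of 23 microglia markers, 5.5 ± 0.707 and 7 ± 0 had a peak in the astrocyte libraries labelled wildtype and knockout, against 7.33 ± 1.15 and 5.67 ± 1.15 in wildtype and knockout neurons. Of 18 vascular markers, 8.5 ± 3.54 and 8 ± 2.83 had a peak in the astrocyte groups in the same order, against 4.33 ± 1.53 and 2.33 ± 0.577 in neurons. In the astrocyte lists the genotype written in the peak names was the opposite of the genotype in the labels, so their directions are given by label throughout.

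The first comparison asked which regions of neuronal chromatin differed between wildtype and Setdb1 knockout cortex. The clustered protocadherins, cell adhesion genes in tandem arrays on chromosome 18 (58 genes, 36930285 to 37841873, mm10), had more accessible positions in knockout neurons. Peaks at these genes made up 0.0215% ± 0.000496 of all peaks (SD, n = 3) in wildtype and 0.0558% ± 0.00327 (n = 3) in knockout libraries, a ratio of 2.59, or 15.7 ± 2.89 against 33 ± 10.4 peaks. Of the 10 protocadherin regions with a peak in exactly 3 of the 6 libraries, 9 were gained, that is present in every knockout and no wildtype library, and 0 were lost.

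The 9 gained regions lay at the lower end of Pcdha7 (36974034 to 36974595) and across the Pcdhg array. Those in the Pcdhg array were next to Pcdhga1 (37655532 to 37656105) and at or beside Pcdhga3, Pcdhga4, Pcdhga5, Pcdhgb4, Pcdhgb5, Pcdhgb7 and Pcdhga11. Of all 53 protocadherin regions, 32 had a peak in more knockout than wildtype libraries, 8 in more wildtype libraries and 13 in equal numbers. By array, 11 of 14 Pcdha genes had a peak at their lower end in at least 1 knockout library and 2 in at least 1 wildtype library. For the 22 Pcdhg genes these counts were 16 and 7, and for the 22 Pcdhb genes 1 and 0. With a peak asked for in every library of a genotype the counts were closer, at 3 knockout and 2 wildtype for Pcdha, 9 and 3 for Pcdhg and 0 and 0 for Pcdhb. The 8 regions present in every library included the ends of Pcdhac1, Pcdhac2 and Pcdhgc3.

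**Figure D2:**
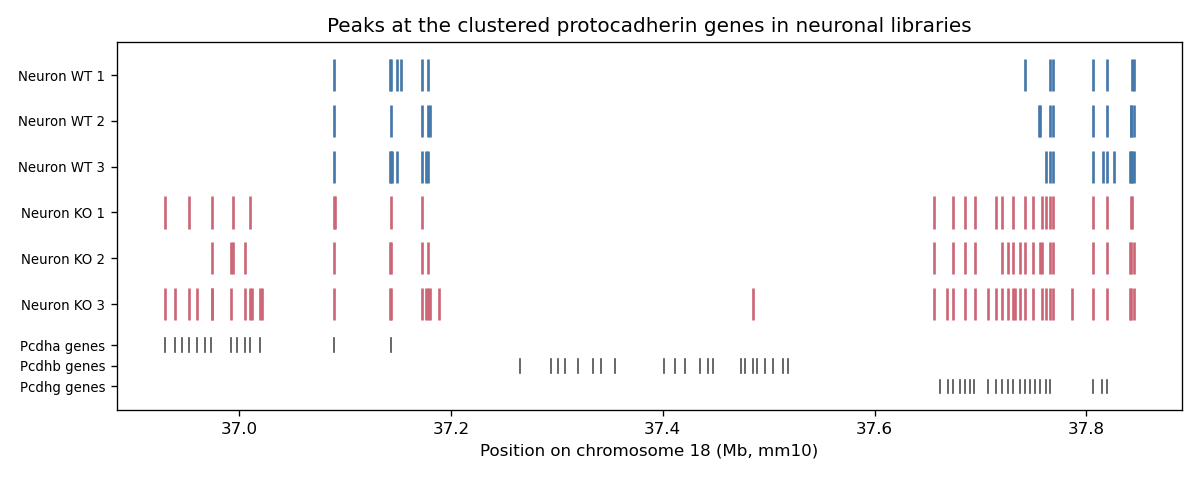
Peaks of each neuronal library (ticks, 1 line per library) along chromosome 18 in Mb (mm10), with the lower ends of the Pcdha, Pcdhb and Pcdhg genes below. Knockout libraries hold 26 to 45 peaks and wildtype libraries 14 to 19, and the added peaks lie at the Pcdha and Pcdhg arrays, with 1 at Pcdhb.

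The enrichment of protocadherins among gained regions gave an odds ratio of 146 (Fisher's exact test over regions, p = 7.40e-11, adjusted p = 3.26e-09 over 44 tests of 22 lists). With every list shortened to the 48122 strongest peaks, 7 of 7 such regions were gained (Fisher's exact test, adjusted p = 9.78e-05). The share of peaks at protocadherins differed in every library of both groups (exact permutation p = 0.1, the smallest possible with 3 against 3, adjusted p = 0.471 over 22 lists). Within sequencing batch 1 the shares were 0.0212% and 0.0539% (means of 2 libraries per genotype), and within batch 2 0.0221% and 0.0595% (1 library per genotype). Regions near each other are not independent, so the Fisher p-values treat as separate what may be 1 domain.

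Across the genome, 634 regions were gained and 1882 lost in knockout neurons, out of 101647 regions of which 36595 had a peak in every library. Some other splits of the 6 libraries gave more than 634 regions in 1 direction (3087, 2198 and 749). With batch as a block the highest other split gave 345. The 10 gained regions with the strongest peaks were led by one 16.2 kb outside Adgrl2, an adhesion G protein-coupled receptor gene (chromosome 3, 148798207 to 148799343, mean fold 10.4 ± 0.370, SD, n = 3). A pair of regions lay inside Prdm6, which encodes a PR domain protein (chromosome 18, 53505265 to 53505709 and 53504072 to 53504527), and others inside Ctnna3 (alpha-T-catenin, chromosome 10, 63593091 to 63593637), Xpo4 (an exportin, chromosome 14, 57656293 to 57657034), Pced1b (chromosome 15, 97255740 to 97256401) and Pgd (chromosome 4, 149152305 to 149152885). The remaining 3 lay outside Moxd2, Slc9a8 and Slc16a1, a monocarboxylate transporter gene. Among the 10 lost regions with the strongest peaks were regions inside Dlg2, a postsynaptic scaffold gene (chromosome 7, 92165131 to 92165807, mean fold 6.71 ± 0.270), Erbb4, a neuregulin receptor gene (chromosome 1, 68134857 to 68135310), and Lingo1 (chromosome 9, 56679333 to 56679656). Others lay outside Nabp1, Gm3072, Gm10376 and Cxcl13, and 3 had no protein-coding gene within 100 kb.

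Besides Pcdha7, Pcdhga3, Pcdhga4, Pcdhga5, Pcdhgb4 and Pcdhgb5, the genes of the fixed lists with a gene end within 1 kb of a gained region were Zfp39 (a zinc finger gene) and Nr4a1 (an activity-induced nuclear receptor). Those at lost regions were Clu, Sox18, Zfp972 and Gad1, the last a gene of GABA synthesis. Lost regions lay at gene ends in 4.78% of cases, against 6.93% of the comparison regions (Fisher's exact test, p = 0.00048, adjusted p = 0.00192 over 4 tests), whereas gained regions did so in 5.84%, against 6.60% (p = 0.508, adjusted p = 0.636).

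The other 21 lists passed the test in neither direction, each with an adjusted p of 1. Of all 10806 comparison regions, 634 were gained and 1882 lost, so more lost than gained regions at a list are no sign of a change at that list. At glutamate receptor and synapse genes 5 of 56 comparison regions were gained and 15 lost, and at GABA receptor and interneuron genes 0 and 6 of 28. At monoamine, stress axis and neuropeptide genes 0 and 5 of 20 were gained and lost, at neuron markers 1 and 5 of 34, and at zinc finger genes 4 and 9 of 71. The counts were 2 and 4 of 21 at imprinted genes, 3 and 2 of 23 at olfactory receptors, 1 and 1 of 10 at activity-induced genes and 1 and 0 of 6 at germline genes. Of the immune lists, interferon response genes had 0 gained and 1 lost of 5, cytokine and inflammasome genes 0 and 1 of 10, and complement and antigen presentation genes 0 and 0 of 4. Glial and vascular lists had 0 and 2 of 9 at astrocyte markers, 1 and 1 of 8 at reactive astrocyte genes, 1 and 1 of 6 at oligodendrocyte lineage markers, 0 and 0 of 2 at microglia markers and 1 and 1 of 9 at vascular markers. SETDB1 partners had 0 and 0 of 7, Hox genes 0 and 0 of 1, housekeeping genes 0 and 0 of 3, and the MAGE and other cancer-testis families no such region. Of the 22 lists, 4 had shares of peaks that did not overlap between genotypes, where chance gives 10%: protocadherins, germline genes (0.0532% in wildtype and 0.0638% in knockout), GABA genes (0.178% and 0.156%) and oligodendrocyte lineage markers (0.0666% and 0.0743%). Germline genes and oligodendrocyte lineage markers overlapped again at equal list length, whereas zinc finger, imprinted and interferon response genes no longer did.

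Of 1050 windows of 1 Mb, 3 held more gained regions than the rest of the genome. These were the protocadherin window (chromosome 18, 37 to 38 Mb, 8 of 9 comparison regions, Fisher's exact test, one-sided, p = 1.15e-09, adjusted p = 1.21e-06), the window of the Cd300 immune receptor genes (chromosome 11, 115 to 116 Mb, 5 of 9, adjusted p = 0.0248) and that of Prdm6, Csnk1g3 and Snx2 (chromosome 18, 53 to 54 Mb, 5 of 9, adjusted p = 0.0248). The Cd300 and Prdm6 windows no longer passed at equal list length (exact test, adjusted p = 0.119 for both), and the windows that did were the protocadherin window (6 of 7, adjusted p = 0.0182) and chromosome 4 from 153 to 154 Mb (6 of 7, adjusted p = 0.0182). With lists as deposited 0 windows held more lost regions, with 30 at an unadjusted p under 0.05.

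Knockout neurons had 58597 ± 14836 peaks and wildtype neurons 72654 ± 11678 (SD, n = 3 each), a ratio of 0.807 (exact permutation p = 0.3 without regard to batch). Knockout libraries were lower within both batches, with ratios of 0.760 in batch 1 and 0.877 in batch 2. With replicate number as a block, which keeps batches together, the exact permutation p was 0.25, the smallest possible with 3 pairs, for peak number, covered sequence and the share of peaks at gene ends. The covered sequence was 25.5 ± 7.37 against 31.8 ± 6.01 Mb and the share of peaks at gene ends 20.6% ± 3.37 against 17.3% ± 1.56 (exact permutation p = 0.3 for both, n = 3 each). With lists of equal length the difference in gene-end share shrank from 3.27 to 0.707 percentage points (exact permutation p = 0.1) and that in covered sequence from -6.32 to -2.19 Mb (exact permutation p = 0.4). At equal list length the balance of gained and lost regions turned, from 634 gained and 1882 lost (25.2% gained) to 964 gained and 546 lost (63.8% gained). Within batch 1, 1138 regions were gained and 7303 lost with 50109 against 65917 peaks, or 2343 and 2218 at equal list length, and batch 2, with 75574 against 86128 peaks, held 1 library per genotype. Libraries of the same genotype had a mean Jaccard index of 0.592 and those of different genotype 0.568, and 3 of the 10 splits of the 6 libraries gave a difference as large. Of the 6 splits that keep 1 library of batch 2 on each side, a block chosen after seeing the data, the real one gave the largest difference (exact permutation p = 0.167, the smallest possible).

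The next comparison asked which regions differed between HEK293T cells with and without SETDB1. Zinc finger clusters on chromosome 19 and the protocadherin cluster on chromosome 5 had more accessible positions in the knockout cells. Peaks in the zinc finger clusters made up 0.490% ± 0.00975 of all peaks (SD, n = 3 wells) in control and 0.764% ± 0.0479 (n = 3) in knockout cells, a ratio of 1.56. Of the 105 regions there with a peak in exactly 3 of the 6 libraries, 80 were gained and 11 lost. At the protocadherin cluster (2 Mb of chromosome 5 from 140 Mb on, hg38) the shares were 0.120% ± 0.00384 and 0.177% ± 0.00618 (n = 3 each), and 19 of 24 such regions were gained and 1 lost.

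The zinc finger clusters, a set of 5 stretches fixed before the data were examined, differed among themselves. From 19 to 25 Mb, 42 of 48 comparison regions were gained and the peaks numbered 77 ± 2 in control and 150 ± 22.5 in knockout cells (SD, n = 3 each). From 52 to 54 Mb, 18 of 19 were gained, with 46 ± 2.65 and 79 ± 9.54 peaks. From 36 to 39 Mb and from 56 to 59 Mb, 8 of 13 and 8 of 10 were gained, whereas from 43 to 45 Mb 4 of 15 were gained and 4 lost, with 98.3 ± 8.39 and 88 ± 6.24 peaks. In the HLA region (chromosome 6, 29 to 34 Mb), which holds the antigen presentation genes, 1 of 16 regions was gained and 5 lost, with 109 ± 12.5 and 71.7 ± 27.3 peaks. Around SETDB1 (2 Mb of chromosome 1 from 150 Mb on), 3 of 10 were gained and 5 lost, with 109 ± 2.08 and 83.7 ± 6.43 peaks.

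**Figure D3:**
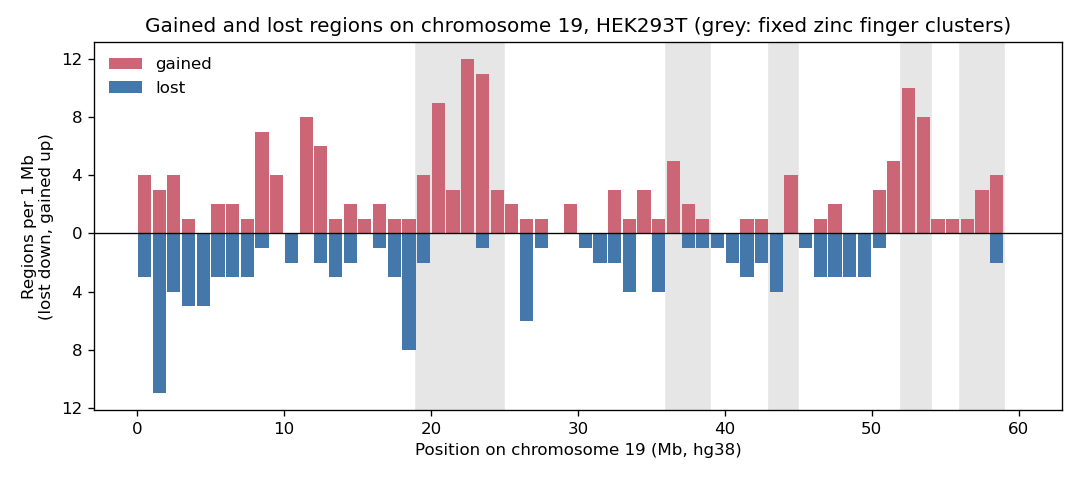
Regions gained (upward) and lost (downward) per 1 Mb along chromosome 19 (position in Mb, hg38) in SETDB1 knockout HEK293T cells. Grey bands mark the 5 fixed zinc finger clusters, and 12 regions were gained and 0 lost from 22 to 23 Mb.

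Gained regions were enriched in the zinc finger clusters (Fisher's exact test over regions, odds ratio 11.6, p = 2.73e-32, adjusted p = 2.18e-31 over 8 tests) and in the protocadherin cluster (odds ratio 13.6, p = 4.05e-09, adjusted p = 1.62e-08). Against regions of the same chromosome only, a setting chosen after seeing the data, Fisher's exact test gave p = 7.07e-23 and p = 3.14e-08. Around SETDB1 the same test gave an odds ratio of 5.86 for gained regions (unadjusted p = 0.0274, exact), and p = 0.105 at equal list length. Against regions of all chromosomes, the HLA region and the surroundings of SETDB1 passed in neither direction (adjusted p of 0.355 and 1 for HLA, 0.533 and 0.432 for SETDB1). The HLA region had 0 of 14 regions gained at equal list length (Fisher's exact test, adjusted p = 0.0148). Shares of peaks in the zinc finger and protocadherin clusters did not overlap between groups (exact permutation p = 0.1 for each, adjusted p = 0.133 over 4 loci, smallest possible 0.1). The share around SETDB1 did not overlap either, in the opposite direction, with 0.137% ± 0.00803 in control and 0.125% ± 0.00714 in knockout cells (exact permutation p = 0.1, n = 3 each). This ratio of 0.906 lay above the 0.761 of the whole of chromosome 1, which holds SETDB1. The lower share is therefore no loss particular to this locus. At equal list length the HLA share did not overlap either, with 0.146% in control and 0.102% in knockout cells. Chance separates the groups so in 10% of cases.

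Of 1477 windows of 1 Mb, 28 held more gained regions, of which 7 lay on chromosome 19, and 23 held more lost regions, of which 19 lay on chromosomes 1 and 7 (Fisher's exact test, one-sided, adjusted over windows). The leading windows of gain were chromosome 19 from 22 to 23 Mb (12 of 12, exact p = 1.26e-08), the 1 Mb of chromosome 5 that starts at 141 Mb (13 of 15) and chromosome 19 from 23 to 24 Mb (11 of 12), the last equal in p to chromosome 7 from 63 to 64 Mb. The leading windows of loss were chromosome 3 from 117 to 118 Mb (11 of 11, exact p = 7.11e-06), followed by 10 of 10 on chromosome 1 from 21 to 22 Mb and from 193 to 194 Mb and on chromosome 7 from 28 to 29 Mb.

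Chromosome 1 held 11.96% ± 0.134 of the peaks in control and 9.11% ± 0.116 in knockout cells (SD, n = 3 each), and chromosome 7 6.77% ± 0.102 and 5.35% ± 0.145. Higher shares in knockout cells were found for chromosome 9 (3.23% ± 0.00984 and 4.26% ± 0.0314), the X (3.13% ± 0.138 and 4.18% ± 0.121) and chromosome 2 (6.65% ± 0.0328 and 7.66% ± 0.196). Smaller differences of the same p were higher shares of chromosomes 5 (6.97% and 7.73%), 12, 14 and 21 (1.05% and 1.24%) and lower shares of chromosomes 6, 11 (4.57% and 4.13%) and 15. Each of these 12 differences gave an exact permutation p of 0.1, the smallest possible (adjusted p = 0.192 over 23 chromosomes), where chance gives 10% of chromosomes. The shares are parts of the same total, so the falls on chromosomes 1 and 7 by themselves raise the shares of the others. The 12 differences are therefore not independent, and small rises such as those of chromosomes 12 and 14 need not be changes there.

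In all, 3272 regions were gained and 5068 lost in SETDB1 knockout cells, and the gained region with the strongest peaks lay on chromosome 7 (82649794 to 82650729, mean fold 12.7 ± 0.655, SD, n = 3). Other strong gained regions lay on chromosome 10 (86337972 to 86338397), chromosome 7 (152697475 to 152698177), chromosome 14 (90153894 to 90154639) and the X (135767739 to 135768428 and 135871478 to 135872065). The lost region with the strongest peaks was on chromosome 1 (95911626 to 95912377, mean fold 11.2 ± 0.761, n = 3), and of the 10 strongest lost regions 4 were on chromosome 1. At equal list length 3791 were gained and 3073 lost, which moved the gained share from 39.2% to 55.2%. Peaks numbered 67518 ± 9309 in knockout and 79711 ± 4874 in control cells (exact permutation p = 0.3, n = 3 each) and covered 30.9 ± 5.09 and 39.6 ± 1.73 Mb (exact permutation p = 0.1), a difference of -8.68 Mb that shrank to -4.92 Mb at equal list length. Within groups the mean Jaccard index was 0.561 and between groups 0.469, and no other split of the 10 gave a difference as large. Each group was 1 cell line sampled as wells, so the permutation p-values measured the spread between wells. The Fisher p-values counted regions and held no spread between wells. Regions near each other are not independent, so they treat as separate what may be fewer domains. A difference between lines was not separable from the knockout.

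The last pair of groups were the astrocytes, labelled wildtype or Setdb1 knockout. No gene list differed between them beyond chance after adjustment. At the clustered protocadherins, 1 of 5 comparison regions was gained in the libraries labelled knockout and 2 were lost, with shares of peaks of 0.0333% ± 0.00307 in libraries labelled wildtype and 0.0395% ± 0.00278 in those labelled knockout (SD, n = 2 each). The gained region lay at Pcdhga2 and the lost ones at Pcdhac2 and Pcdhgb7. A cluster of gained regions lay around Epha3, an ephrin receptor gene, where 5 of 5 comparison regions were gained (chromosome 16, 63 to 64 Mb, Fisher's exact test, one-sided, p = 4.79e-06, adjusted p = 0.00383 over 801 windows).

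The Epha3 window no longer passed at equal list length (5 of 6, adjusted p of 1), and no other window passed in either direction, with 15 gained and 19 lost windows at an unadjusted p under 0.05. In the libraries labelled knockout, 774 regions were gained and 3403 lost, out of 66174. The gained region with the strongest peaks lay 26.9 kb outside Lbx1 (chromosome 19, 45204744 to 45205791, mean fold 10.7 ± 0.297, SD, n = 2). Others were beside Abca13, Nmi, an interferon-related gene, and Anxa3, and inside Ctnna3 (chromosome 10, 63593095 to 63593598), St6galnac3, 4933424G06Rik and Lrrtm4. The strongest lost regions lay inside Qprt, an enzyme gene of the kynurenine pathway (chromosome 7, 127110666 to 127110973, mean fold 11.1 ± 0.538), and inside Gpatch8, Ctnnd2, Cyp26b1, Lrrc4c, Btla, Mbnl1 and Lsamp, with others outside Fcgr3 and Lao1.

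Among genes of the fixed lists, Zfp445, Tmem119, Olfr1033, Oasl2, Ly6c1 and Ifit1 had a gene end within 1 kb of a gained region, Oasl2 and Ifit1 being interferon-induced genes. Genes at lost regions included Tubb3, Olig2, Nlrc5, Cfb, Hoxb8, Npy, Magel2 and Sgk1. In the tests of 22 lists in both directions, 4 gave an unadjusted p under 0.05 (Fisher's exact test). Of all 8948 comparison regions, 774 were gained and 3403 lost. A smaller share was lost at interferon response genes, with 2 of 9 gained and 0 lost (exact p = 0.0160 for lost, adjusted p = 0.365). The lost share was also smaller at vascular markers, with 1 of 17 gained and 2 lost (Fisher's exact test, p = 0.0249 for lost, adjusted p = 0.365). A larger share was gained at olfactory receptors, with 3 of 7 gained and 2 lost (exact p = 0.0173 for gained, adjusted p = 0.365). A larger share was lost at zinc finger genes, with 8 of 93 gained and 45 lost (Fisher's exact test, p = 0.0415 for lost, adjusted p = 0.457).

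The remaining lists gave adjusted p-values of 0.784 or more. At glial lists, 0 of 10 regions at astrocyte markers were gained and 6 lost, 2 of 13 at reactive astrocyte genes gained and 3 lost, 1 of 16 at oligodendrocyte lineage markers gained and 9 lost, and 1 of 3 at microglia markers gained and 1 lost. At immune lists, cytokine and inflammasome genes had 0 gained and 0 lost of 6, and complement and antigen presentation genes 0 and 3 of 5. At neuronal lists the counts were 1 and 6 of 16 at neuron markers, 2 and 10 of 24 at glutamate genes, 0 and 3 of 6 at GABA genes, 1 and 5 of 11 at monoamine, stress axis and neuropeptide genes and 0 and 1 of 5 at activity-induced genes. Imprinted genes had 1 and 4 of 9, SETDB1 partners 1 and 1 of 6, Hox genes 0 and 2 of 3, germline genes 0 and 1 of 2, the MAGE and other cancer-testis families 0 and 1 of 2, and housekeeping genes 0 and 0 of 1.

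The libraries labelled knockout had 45568 ± 371 peaks over 20.2 ± 0.113 Mb and those labelled wildtype 52672 ± 2730 over 23.8 ± 1.06 Mb (exact permutation p = 0.333, the smallest possible with n = 2 each). Peaks at gene ends made up 25.2% ± 0.334 and 22.6% ± 0.945 (exact permutation p = 0.333, n = 2 each). With lists of equal length the difference in gene-end share shrank from 2.59 to 0.526 percentage points and that in covered sequence from -3.58 to -1.63 Mb. Lost regions lay at gene ends in 7.88% of cases against 8.84% of comparison regions (Fisher's exact test, p = 0.118, adjusted p = 0.236) and gained regions in 8.91% against 8.43% (p = 0.636, adjusted p = 0.636). At equal list length 1566 were gained and 1783 lost, so the gained share moved from 18.5% to 46.8%, and the gained regions lay at gene ends in 10.3% of cases (Fisher's exact test, adjusted p = 0.0284). Other splits of the 4 libraries gave up to 1696 regions in 1 direction as deposited and 1232 at equal length, and the mean Jaccard index was 0.653 within and 0.632 between groups, with no other split as large.

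Neurons and astrocytes shared a small part of their gained regions. In all, 634 regions were gained in knockout neurons and 774 in the astrocyte libraries labelled knockout, and 50 were gained in both. Only 122 of the regions gained in neurons lay where both cell types had a peak. Among 444 regions that could have been gained or lost in both cell types, 54 were gained in knockout neurons. Of these, 50 were also gained in the astrocyte libraries labelled knockout, against 7.91 expected of independent lists, a ratio of 6.32 (Fisher's exact test, two-sided, p = 1.29e-47). Ranked by their peaks in neurons, the shared regions were led by those near Adgrl2, in Prdm6, near Slc9a8 and in Ctnna3, Xpo4 and Pced1b, whereas by rank in astrocytes Ctnna3 came first and Slc9a8 ranked low (24.2). Only 1 region gained in neurons overlapped a region lost in the astrocyte libraries. The 23 regions lost in both were as many as independent lists give (22.7 expected, Fisher's exact test, p = 1), and 2 were lost in neurons and gained in astrocytes. Lists of equal length gave 71 regions gained in both, against 30.6 expected, a ratio of 2.32. Same-direction overlaps numbered 73 and crossed ones 3 (Fisher's exact test, p = 4.07e-16), or 76 and 8 at equal list length (p = 0.000143), where 5 regions were lost in both.

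**Figure D4:**
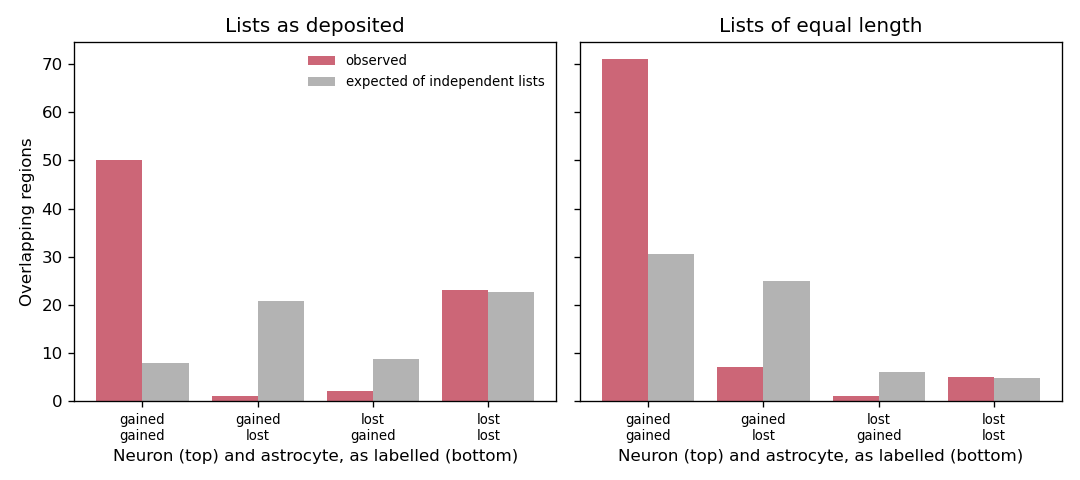
Regions gained or lost in neurons that overlap regions gained or lost in astrocytes, by label (vertical axis, number of regions), with lists as deposited and at equal length. Red bars are observed and grey bars expected of independent lists, and the 50 regions gained in both stand against 7.91 expected, an excess that by itself lowers the crossed counts.

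The change in peak number did not differ detectably between the cell types, with log2 ratios of knockout to wildtype of -0.31 in neurons and -0.21 in astrocytes (difference -0.10, exact permutation p = 0.767). For the protocadherin share the difference between the cell types was 0.0281 percentage points (exact permutation p = 0.1, adjusted p = 0.575 over 23 measures).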

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

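Of the tests in this part, those of list length, chromosome bins, exchanged labels and distance from Setdb1 were chosen after the result was seen.

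The share of peaks at oligodendrocyte lineage markers moved differently in the cell types, by 0.0309 percentage points (0.00771 in neurons and -0.0232 in the astrocyte libraries by label, exact permutation p = 0.0167, the smallest possible, adjusted p = 0.383 over 23 measures), and so did not pass after adjustment. Peaks on sequences outside the chromosomes, which no comparison used, took a higher share in mouse knockout libraries. They made up 0.130% ± 0.0112 of peaks in knockout and 0.115% ± 0.00878 in wildtype neurons (SD, n = 3 each, exact permutation p = 0.1), although their number was 65 to 93 against 70 to 104, so in neurons the higher share went with shorter lists. In astrocyte libraries they made up 0.181% ± 0.00920 of those labelled knockout and 0.137% ± 0.0205 of those labelled wildtype (n = 2 each, exact permutation p = 0.333), and their number was higher too, with 80 and 85 against 67 and 77. In HEK293T cells the shares were 2.57% ± 0.128 in knockout and 2.54% ± 0.193 in control cells (n = 3 each, exact permutation p = 0.8).

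The gained regions at zinc finger and protocadherin clusters of knockout HEK293T cells were weighed against copy number. In the 2 Mb on both sides of these loci 13.5% of comparison regions were gained (24 of 178), against 76.7% at the loci (99 of 129, Fisher's exact test, p = 3.19e-30), which argues against extra copies of wider stretches. At equal list length 104 were gained, against 99 as deposited. Knockout lists were the shorter on average (67518 against 79711 peaks), so equal length removes mainly control peaks. Gained regions of the whole genome rose too, from 3272 to 3791. The count at the loci was thus not likely to fall, and it cannot decide on list length. An effect of the knockout may underlie them, but a difference between the lines that arose without it was not tested and stays open.

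The lost regions on chromosomes 1 and 7 of knockout HEK293T cells spread along both chromosomes. In 95% of 40 bins of 10 Mb the lost share was above that of the rest of the genome, with 84.2% over both chromosomes against 54.5% elsewhere. Fewer copies of both chromosomes in the knockout line are a candidate explanation. Copy number itself was not measured, and an effect of SETDB1 on whole chromosomes stays open.

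The regions gained in both neurons and the astrocyte libraries labelled knockout were weighed against exchanged labels, since the peak names name the opposite genotype. Of the neuron-gained regions, 1 overlapped a region lost in the astrocyte libraries and 50 a gained one, which argues against an exchange of the labels if the shared regions follow genotype. Of these 50, 0 lay within 20 Mb of Setdb1, and at equal list length 1 of 71 did (Fcgr1, 0.964 Mb away), which argues against sequence carried along with the allele for most of them. Neuronal nuclei in the astrocyte libraries, which the purification by ACSA-2 should remove, cannot be told apart from a shared effect: 9.30% of 86 neuronal marker regions of like rank had a peak in both libraries labelled knockout, against 12.3% of neuron-gained regions (Fisher's exact test, p = 0.483). In both libraries labelled wildtype the shares were 12.8% and 3.94%, so marker regions were not more frequent in those labelled knockout, but neuronal nuclei of each genotype in both groups stay open. An effect of the knockout in both cell types may explain the overlap, and sequence differences between the colonies, elsewhere in the genome, were not tested.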

How the results depend on the processing

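Gene-end shares, counts at protocadherins and zinc finger clusters, and tests within a chromosome were chosen after seeing the data, as was the expected overlap of the cell types over regions that could have been gained or lost in both. The planned expectation over all regions with a peak in both gave ratios of 38.8 for regions gained in both and 1.78 for regions lost in both, against 6.32 and 1.01. Of the alternatives other than leaving a library out, 109 values were labelled the same, 24 moved, 1 reversed and 1 became stronger. The same meant a similar size for counts and an equal sign for differences, so it says nothing of significance. Only odds ratios at gene ends were also judged by p under 0.05. Blocks by batch or replicate keep the counts of gained and lost regions by construction, so these could only be the same. Depth limits absence: a region without a peak may hold reads, so more lost regions could follow from shorter lists. Equal list length left 546 lost neuronal regions, but it removes an excess of lost regions whatever its cause. It therefore cannot tell shorter lists from a loss of accessibility. Causes were not tested except where stated.

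At equal list length the neuronal counts were 964 gained and 546 lost, the HEK293T lost regions 3073 and windows 25 (51 as deposited), the astrocyte counts 1566 gained and 1783 lost, lists apart 7 (11 as deposited) and windows 0, and regions lost in both cell types 5. With 2 libraries against 2, as in astrocytes, chance alone sets 33.3% of the 22 lists apart. Differences in covered Mb shrank to -2.19 in neurons, -4.92 in HEK293T cells and -1.63 in astrocytes, and in gene-end share to 0.707 and 0.526 points in neurons and astrocytes. The log2 odds ratio of gained regions at gene ends reversed to 0.23 in neurons (-0.19 as deposited, neither past the test) and became stronger at 0.34 in astrocytes (0.09 as deposited). With a stricter threshold for presence than for absence, which by construction admits fewer regions, 753 were lost in neurons, 1938 gained and 1943 lost in HEK293T cells, and 260 gained and 1939 lost in astrocytes. A -log10 q of 5 left 463 gained in astrocytes, with a difference in gene-end share of 3.94 points. Batch 1 gave 1138 gained and 7303 lost in neurons, where fewer libraries must show a peak. Windows of 2 Mb gave 6 in neurons and 0 in astrocytes.

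Leaving out 1 library lets more regions qualify by construction. Neurons then had 689 to 1164 gained (996 without wildtype 3, 1164 without knockout 1, 1009 without knockout 2) and 2287 to 6446 lost (3993 and 4267 without wildtype 1 and 2, 6446 without knockout 3). HEK293T cells had 3701 to 5151 gained (5151 without knockout 2) and 6124 to 8444 lost (8444 and 7860 without control 1 and 3, 8434 without knockout 1). Astrocytes had 1568 to 3326 gained (2135 and 1568 without the libraries labelled wildtype 1 and 2, 2971 and 3326 without those labelled knockout 1 and 2) and 6316 to 9736 lost (7505, 9736, 6316 and 6317 in that order). Differences in neuronal peak number were -22545 to -7319 (-7319 without wildtype 3, -8819 without knockout 1, -22545 without knockout 3), in covered Mb -10.5 to -2.86 (-2.86, -3.76 and -10.5 in that order) and in gene-end share 1.87 to 5.14 points (1.87 without knockout 1, 5.14 without knockout 3). In HEK293T cells peak number gave -17547 to -9112 and covered Mb -11.6 to -7.04, and in astrocytes covered Mb -4.33 to -2.83 and gene-end share 1.92 to 3.26. Gained protocadherin regions were 9 to 13 in neurons, 20 to 25 in HEK293T cells and 2 to 3 in astrocytes, and zinc finger regions 83 to 105.

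Taken as deviations from their group means, wildtype and knockout libraries of the same replicate number correlated at 0.0180, 0.0704 and 0.117 in neurons. Those of different number correlated at -0.0973 to 0.0417. These values do not measure the likeness of whole lists, for which the Jaccard index between neuronal genotypes was 0.472 to 0.650. The highest correlation, 0.117, was that of replicate 3, both libraries of batch 2. In HEK293T cells the values were 0.00569, 0.0104 and -0.000237, against -0.0135 to 0.00845 for different numbers. The 0.0407 and -0.0407 of astrocytes are opposite by construction with 2 libraries per group. Whether replicate numbers pair the samples was not tested. With replicate number as a block, the highest other split gave 258 regions in 1 direction in neurons, 954 in HEK293T cells and 1253 in astrocytes, and with batch as a block 345 in neurons. Promoter shares and gene extensions were not run for HEK293T cells, for want of an annotation.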

Other observations

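The settings of splits, list length and batch were planned for all gained and lost regions. Their use here to weigh an explanation, and the counts at protocadherins and zinc finger clusters, were chosen after the result was seen.

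With 10 splits of 6 libraries, splits are too few for a share under 0.05. For all gained and lost regions the real split gave 2516 in neurons, and 2 splits gave as many, the other one 3105. That split set wildtype 1 and 3 and knockout 3, the longest lists and among them both libraries of batch 2, against the rest, so it points to a structure of the samples in which list length and batch go together. Shortened to equal length it gave 875, still the highest of the others, and the real split 1510, and with batch as a block the highest other split gave 345 in 1 direction as deposited. In HEK293T cells 1 split, the real one, gave as many as 8340, and the highest other gave 1046. For protocadherin regions in neurons 1 split gave as many as 9 gained (highest other 1), and for zinc finger regions in HEK293T cells 1 split gave as many as 80 (highest other 2).

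More regions were lost than gained in neurons as deposited, but 546 were lost and 964 gained at equal list length. Within batch 1 the excess of lost regions was present as deposited, with 7303 lost and 1138 gained, and absent at equal list length, with 2218 lost and 2343 gained. Since equal list length removes such an excess whatever its cause, the source of the excess stays open.

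Of the 50 regions gained in both mouse cell types, 6 lay on the X, all from 123500308 to 126000389, and the 50 lay on 18 chromosomes. Regions so close are not independent, so the p-values of the overlap are too small.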
